A study of Arabidopsis thaliana with 6 samples.

How the data were processed

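RNA of 2-week-old Arabidopsis thaliana seedlings was measured on 6 Affymetrix ATH1 arrays, 1 per sample, 3 labelled wild type (accession Col-0) and 3 labelled ASL9-ox. The tissue label names aerial parts, while the extraction protocol speaks only of harvested seedlings and does not mention the removal of roots. ATH1 carries short oligonucleotides grouped into probe sets, each of which reads 1 transcript or a few related ones. The deposited table held 22810 probe sets for each of the 6 arrays. Per the submitters' processing notes, MAS5 and GCOS, Affymetrix programs that subtract background and combine the oligonucleotides of a probe set, were used by the authors to make the intensity values, and their versions are not given in the sources used here. The values were linear, and the mean of each array without the lowest and highest 2% was 100.01, so the arrays had been scaled to a common mean. Such scaling holds the mean of every array at 1 level, so a shift of all transcripts in 1 direction is not visible in it. No detection calls came with the values used here, and dim values could not be set against a background call. From 36.8% to 37.9% of the probe sets lay below a signal of 16 on each array.

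Probe sets were named only through the platform annotation supplied with the data. It paired 13513 probe sets with 1 gene and 503 with several genes, and the remaining 8794 were unnamed here. Of the former, 13436 matched a gene of the RefSeq table for assembly TAIR10.1, from which current symbols were taken, and they covered 13356 genes. No probe set was paired with ASL9 (0 listed). The planned check of the labels through the overexpressed gene, and its fold change, could therefore not be made, and every direction given rests on the labels alone.

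Values were transformed to log2(signal + 16). A fold change on this scale understates the change of genes with low signals. The 64 Affymetrix control probe sets and the dimmest 25% of the others by mean over all 6 arrays were left out, which left 17059. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all 17059 probe sets and a threshold of 0.05. The prior carried 5.11 degrees of freedom. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 3 arrays per group, the number of arrays limits the precision. On simulated data with the same means and spreads, the procedure called 23 of 67 probe sets changed by 0.5 on the log2 scale. It called 60 of 67 changed by 1, 66 of 66 changed by 2, and 10 of 16851 unchanged ones, among 17059 tested. Nearly all probe sets were left unchanged there, with noise independent between them, whereas 41.6% passed in the real comparison. These rates therefore need not carry over to it.

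There were 33 gene lists, fixed before the data were examined and matched by symbol or synonym, with 1 probe set per gene (that with the highest mean). Of 858 matched names, 108 had a probe set paired with that gene alone, because the annotation used left most genes with a symbol unnamed. The lists were therefore sampled thinly. The list of cytosolic ribosomal proteins could not be built, because the gene table carried no descriptions, and those of auxin transport, nitrate response and phosphate starvation had no measured member. The 14 lists with at least 3 tested members were compared with all other probe sets by limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 14), with an estimated correlation as an alternative. The lists were also tested with fry, which asks whether the members of a list move, on balance, in 1 direction and does not compare the list with other genes. The rule for named genes took, among probe sets past the threshold, paired with 1 gene and without overlap between the groups, the 12 with the largest rise and the 12 with the largest fall, then up to 4 members per list past the threshold with the largest change, or the member with the smallest p where none passed. Other genes named in the text were chosen after their values were seen.

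The alternatives fixed before the data were examined were quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no filter and a filter of the dimmest 50%, eBayes without a trend and with robust estimation, array weights, the replicate number as a block, each array left out in turn, a threshold of 0.01, and the mean of a gene's probe sets in the lists. Centring on the bacterial and phage control transcripts added at hybridization (9 probe sets) and a test of gene families by symbol were added after seeing the data. Figures were drawn with matplotlib 3.10.9.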

Results

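Transcript levels were compared between wild-type Arabidopsis seedlings and seedlings of a transgenic line that overexpresses ASL9, which is also known as LBD3 (AT1G16530) and belongs to the plant-specific LBD family of transcription factors. The plants were grown upright on agar medium for 2 weeks and the profiled tissue was labelled as aerial parts, with 3 arrays in each group. The extraction protocol speaks only of harvested seedlings. The comparison asked which transcripts differ in the presence of the transgene. Log2 signals correlated at 0.9794 to 0.9926 between arrays of the same group and at 0.9275 to 0.9531 between arrays of different groups (Pearson, across probe sets, which are not independent). The 3' to 5' signal ratio of the actin control lay between 1.55 and 1.81 on the 6 arrays, and that of the GAPDH control between 0.866 and 1.06. No probe set was paired with ASL9 in the annotation used, so its level could not be used to check the labels. The direction of every change rests on these labels, which an unnamed probe set described below leaves in doubt. Here "rose" and "fell" mean higher or lower in the arrays labelled ASL9-ox than in those labelled wild type, with an adjusted p below the threshold of 0.05 in limma's moderated test.

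A large part of the measured transcriptome differed between the groups, and most changes of at least 8-fold were falls. Fold changes, and every ranking by size, are on the log2(signal + 16) scale, on which the added 16 sets the fold of a gene whose signal in 1 group lies near or below 16. The osmotin-like gene OSM34 fell from a signal of 2064 ± 101 to 13.1 ± 7.69 (SD, n = 3 per group), a log2 fold change of -6.19 ± 0.15 (SE). Of the 17059 probe sets tested, 7096 (41.6%) passed the threshold, 4203 of them higher and 2893 lower. Changes of at least 2-fold were found for 1218 of these, of which 445 rose and 773 fell. Changes of at least 8-fold were found for 4 that rose and 72 that fell. The ranges of the 2 groups did not overlap for 9204 probe sets (54%), where chance gives 10%. For none of the 106 genes read by several tested probe sets were calls made in both directions (0 genes). Only genes with more than 1 called probe set could show this, and their number was not counted. The number of higher calls depended on the scaling. When arrays were instead centred on the hybridization controls, which differed by 0.092 on the log2 scale between the groups, 2353 probe sets rose and 3100 fell. The higher ones then made up 43.2% of the calls in place of 59.2%. The mean of these controls ran from 7.819 to 8.014 over the arrays labelled wild type and from 7.947 to 8.095 over those labelled ASL9-ox. The groups overlapped in it, so the difference of 0.092 may be spread between arrays. The count of 2-fold changes was 2098 with a pseudocount of 1 and 543 with a pseudocount of 64.

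Besides OSM34, the 12 largest falls among probe sets paired with 1 gene included AT5G44380 and AT1G30700, which encode berberine bridge enzyme-like oxidases, with log2 fold changes of -4.74 ± 0.09 and -4.73 ± 0.10 (SE). The signal of AT1G30700 went from 427 ± 53.6 to 0.587 ± 0.174 (SD, n = 3 per group). A peroxidase gene, AT5G64120, fell from 1224 ± 235 to 32 ± 11.3, and a second one, AT2G18980, from 409.5 ± 46.6 to 11.3 ± 3.47. ChiC, which encodes a chitinase, fell from 709 ± 109 to 35.9 ± 3.71, and the jacalin-related lectin gene JAL33 from 969 ± 134 to 53.4 ± 3.49. SAG29, which encodes the sugar transporter SWEET15, fell from 437 ± 61.4 to 5.87 ± 5.23. The other 4 were AT4G22470 (log2 fold change -5.56), AT3G46280 (-4.10), AT2G19970 (-4.02) and AT1G74010 (-3.86). All 12 had adjusted p-values between 5.76e-09 and 4.06e-07.

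The largest rises were smaller on the log2(signal + 16) scale. AT1G67865 had the largest on that scale among probe sets paired with 1 gene, from a signal of 72.5 ± 23.1 to 943 ± 15.8 (SD, n = 3 per group), a log2 fold change of 3.47 ± 0.15 (SE, adjusted p = 4.60e-07). The signals of AT2G32160 and AT5G62280 in the arrays labelled wild type, 3.39 and 11.2, lay below 16, so their place among the rises depends on the number added. The cell wall loosening gene EXPA8 rose from 34.3 ± 0.61 to 427 ± 55.8, and COR15B, which encodes a cold-induced chloroplast protein, from 34.3 ± 16.6 to 383 ± 152. AT5G55450, a lipid transfer protein gene, rose from 49.7 ± 10.3 to 424 ± 136. AT3G22240 went from 386 ± 199 to 2709.5 ± 692. The remaining 7 were AT3G16670 (log2 fold change 3.19), AT2G32160 (2.89), AT5G62280 (2.67), AT1G19960 (2.52), AT5G22580 (2.50), AT5G61660 (2.46) and AT5G07030 (2.46).

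**Figure D1:**
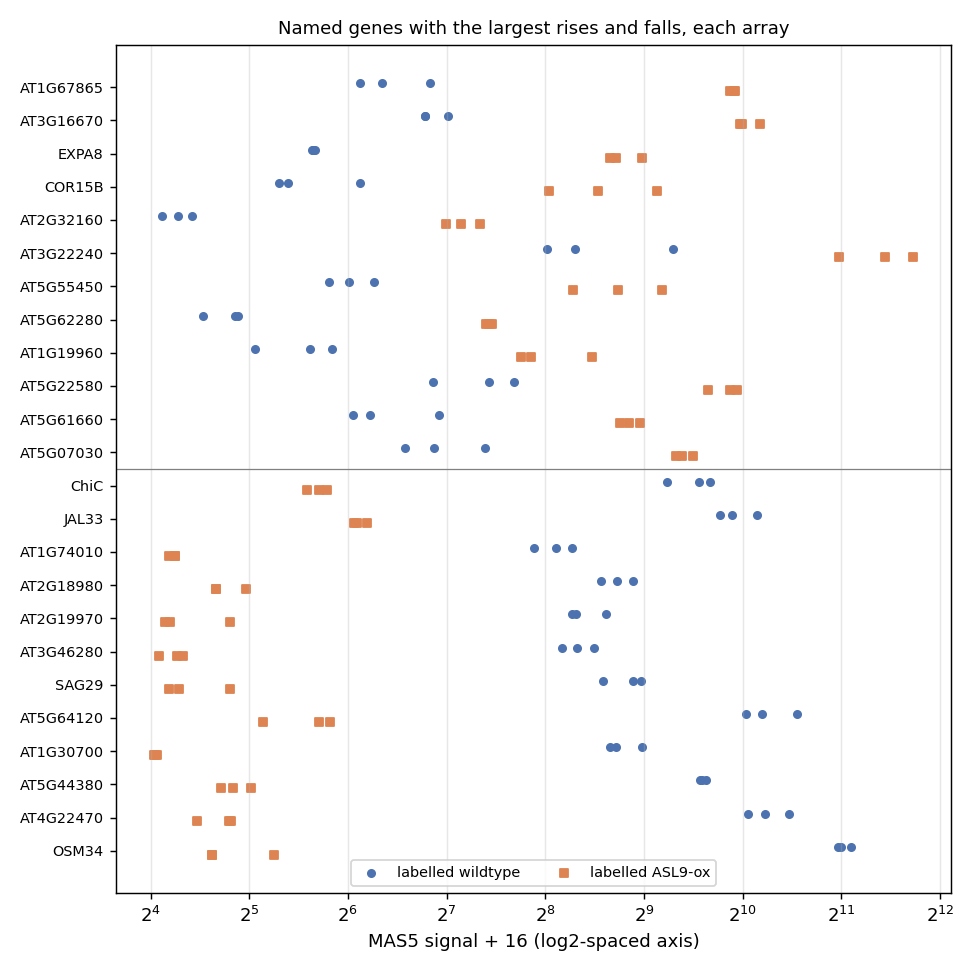
Signal plus 16 on each array, on a log2-spaced axis, for the 12 genes with the largest rises (upper part) and the 12 with the largest falls (lower part). Circles are the 3 arrays labelled wild type and squares the 3 labelled ASL9-ox; in every gene drawn the 2 groups lie apart, and OSM34 goes from 2064 to 13.1.

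Probe sets without a gene name in the annotation used also changed. The probe set 262704_at read 5101 ± 162 in the arrays labelled wild type and 10.9 ± 3.56 in those labelled ASL9-ox (SD, n = 3 per group), a log2 fold change of -7.58 ± 0.10 (SE, adjusted p = 6.96e-10). This was the largest change on the log2(signal + 16) scale, with a signal below 16 in the arrays labelled ASL9-ox. A second one, 260101_at, went from 2871 ± 147 to 18.9 ± 11.4. In 5 probe sets the median signal went from above 1000 in the arrays labelled wild type to below 16 in those labelled ASL9-ox, and in 0 it went the opposite way. Among probe sets with a median below 16 in the arrays labelled wild type, the highest median in those labelled ASL9-ox was 160.6 (263549_at). If 262704_at read the transgene's transcript, exchanged group labels could give its pattern, a possibility taken up below that could not be decided.

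Genes of the photosynthetic apparatus were higher in the arrays labelled ASL9-ox. All 3 measured members of the light-harvesting antenna list rose, LHCB4.3 from 135 ± 3.3 to 297 ± 28.7, LHCB4.2 from 2329.7 ± 207 to 4340 ± 168 and LHCB4.1 from 3860.1 ± 131 to 5299.5 ± 249 (SD, n = 3 per group). All 8 measured members of the photosystem and carbon fixation list rose as well, by 0.18 (RCA) to 0.66 (PSAN) on the log2 scale. The highest signal per array was 6617 to 7196 on the arrays labelled ASL9-ox and 5493 to 5796 on those labelled wild type. A shift shared by all bright probe sets was not separated from these small rises. In the chlorophyll synthesis list 6 of 8 members rose. They included PORB, which encodes the light-dependent protochlorophyllide oxidoreductase (1148 ± 173 to 2530 ± 304), and CHLM, a methyltransferase of the magnesium branch (1032 ± 103 to 1576 ± 83.1). GSA1, with a log2 fold change of 0.03, and HEMA2, with 0.26, did not pass. By camera the adjusted p-values of these lists were 0.0126, 0.0126 and 0.0242, and with an estimated correlation they were adjusted p = 0.205, 0.334 and 0.334. With quantile normalization the adjusted p of the photosystem list was 0.0942 (0.00806 to 0.0942 over the alternatives with the preset correlation) and 4 of its 8 members rose; with centring on the hybridization controls 3 of 8 photosystem members and 2 of 8 chlorophyll synthesis members rose.

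Regulators of leaf epidermal cell types also rose, in 4 of 6 measured members of the stomatal and trichome list (camera adjusted p = 0.0255; adjusted p = 0.334 with an estimated correlation). The trichome regulator GIS had a log2 fold change of 1.37 ± 0.10 (SE) and STOMAGEN, which encodes a peptide that promotes stomatal formation, one of 1.13 ± 0.14. SPCH and FMA, which act at the first and the last step of the stomatal lineage, rose by 0.75 and 0.47. MUTE, at -0.12, and TRY, at 0.44, did not pass. With p-values adjusted over the list alone, 5 members rose.

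Cell wall remodelling genes changed in both directions. Of 17 tested expansin and xyloglucan endotransglucosylase genes, 8 fell, 3 rose and 6 did not pass (camera adjusted p = 0.0126, lower; adjusted p = 0.205 with an estimated correlation). XTH18 fell from 132 ± 26.5 to 2.61 ± 2.77, XTH19 from 351 ± 41 to 43.7 ± 12.9 and EXPA4 from 1026 ± 88.8 to 179 ± 16.5 (SD, n = 3 per group), whereas EXPA8 was among the 12 largest rises.

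Hormone-related genes gave a mixed picture. Both tested type-A response regulators, which are induced by cytokinin, rose. RR16 went from 25 ± 5.72 to 74.6 ± 8.45 (log2 fold change 1.15 ± 0.12) and ARR15 from 7.61 ± 5.10 to 36.5 ± 11.9 (1.15 ± 0.20), and the other 8 genes of that list had no probe set paired with them alone in the annotation used. Among genes for auxin-conjugating GH3 enzymes, GH3.17 fell by 2.41, WES1 (GH3.5) fell by 2.26 and GH3.1 fell by 0.73 on the log2 scale, while GH3.3 rose by 0.52. That list passed as lower (camera adjusted p = 0.0242; adjusted p = 0.205 with an estimated correlation). Of 3 Aux/IAA genes, IAA29 rose by 0.54 and the other 2 did not pass. The gibberellin receptor gene GID1B had a log2 fold change of -1.19, whereas GID1A (-0.26) and GID1C (0.22) did not pass. With p-values adjusted over the list alone, 2 members fell. The ethylene signalling genes EIN3 and RTE1 rose by 0.36 and 0.34, and neither passed with centring on the hybridization controls (adjusted p = 0.0978 and 0.138, with ranges over all alternatives of 0.00163 to 0.0978 and 0.00622 to 0.138). The brassinosteroid receptor gene BRL1 fell by 0.53, and UGT76C1, which glucosylates cytokinins, rose by 0.47. Mean signals of IAA29 (7.64 to 18.3), GH3.1 (18.1 to 4.51) and BRL1 (18.8 to 8.10) lay near or below 16. Without detection calls these could not be set against background.

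The flavonoid, glucosinolate and senescence lists passed as lower with the preset correlation. In the flavonoid and anthocyanin list 3 of 5 members fell (4 when adjusted over the list alone), with DFR, an anthocyanin pathway reductase, going from 156 ± 11.1 to 52.8 ± 21.6 and UF3GT from 78.1 ± 18.8 to 19.4 ± 11.6 (SD, n = 3 per group). The camera adjusted p was 0.0242, and it was adjusted p = 0.334 with an estimated correlation and 0.0522 without wildtype replicate 1 (0.0115 to 0.0522 over the alternatives with the preset correlation). In the glucosinolate list BCAT4 and UGT74B1 fell by 0.86 and 0.63, and AOP3, at -0.40, did not pass (camera adjusted p = 0.0242; adjusted p = 0.205 with an estimated correlation). AOP3 read 74.6 on wildtype replicate 2 and at most 11.3 on the other 5 arrays, and without that array the list had too few members to be tested. In the senescence list SAG29 fell by 4.39 and WRKY6 fell by 1.57, and WRKY53, at -0.12, did not pass (camera adjusted p = 0.0126; adjusted p = 0.205 with an estimated correlation). These 2 are a sugar transporter and a transcription factor of senescence and defence.

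Cold and drought genes moved apart. COR15A and COR15B rose by 1.60 and 2.97, LTI30, which encodes a dehydrin, fell by 2.49, and COR47, at -0.10, did not pass. The list did not pass (camera adjusted p = 0.969, lower), although the median of its members was 0.75 and their mean 0.49. The touch and early stress list, in which GSTU25 and CML38 fell by 1.02 and 0.55, missed the threshold (camera adjusted p = 0.0508; 0.0304 to 0.12 over the alternatives with the preset correlation). The Aux/IAA and gibberellin lists (0.230 and 0.211) and that of meristem and leaf polarity genes (0.969) did not pass either, and none of PHV, YAB3 and YAB5 passed (0 of 3). In all, 9 of the 14 lists tested passed, 4 higher and 5 lower. With an estimated correlation in camera 0 passed, 2 of the 14 having an unadjusted p below 0.05.

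**Figure D2:**
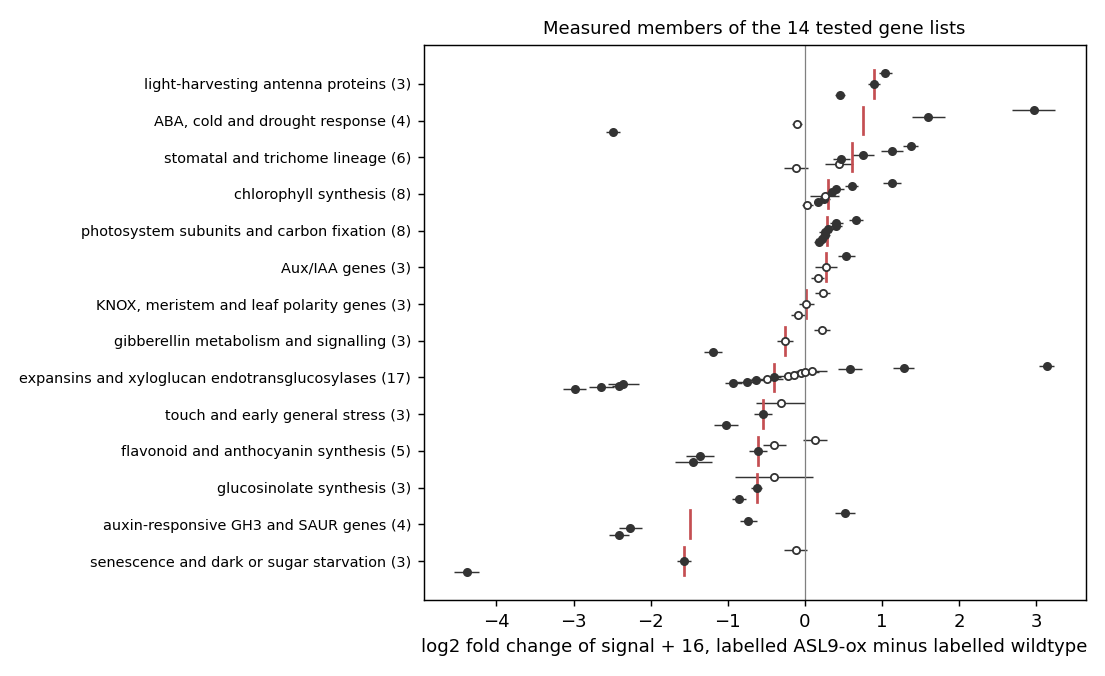
Log2 fold change of signal plus 16, arrays labelled ASL9-ox minus arrays labelled wild type, for each tested member of the 14 gene lists, with bars of 1 SE and the number of members in brackets. Filled points passed the threshold, open ones did not, and the vertical red line is the list's median; the antenna list lies at 0.90 and the senescence list at -1.57.

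Lists with 1 or 2 tested members gave single values. PYK10, a beta-glucosidase gene best known from roots and hypocotyls, fell from 3055 ± 180 to 429.7 ± 22.2 (log2 fold change -2.78 ± 0.07), and the other tested member of the root marker list, EXPA18, had a signal of 6.14 in the arrays labelled wild type. The cell cycle inhibitor gene SIM and the cell cycle gene PRL rose by 0.38 and 0.43, and the clock gene GI by 0.84. The iron regulators BHLH101 and PYE fell by 0.51 and 0.33, and the lignin pathway gene HCT fell by 0.48. The defensin gene PDF1.2 rose from 891 ± 400 to 1773 ± 681, with overlapping groups and an adjusted p of 0.0447, and it missed the threshold under 10 of 17 alternatives (0.003 to 0.191 over all of them), among them those without wildtype replicate 1, wildtype replicate 2, ASL9-ox replicate 1 or ASL9-ox replicate 3. The call for BHLH101 was lost without wildtype replicate 2, without wildtype replicate 3 and without ASL9-ox replicate 1 (0.0742, 0.0516 and 0.0803; 0.0103 to 0.0803 over all alternatives). SIM missed the threshold with centring on the hybridization controls (0.0621; 0.0065 to 0.0621). GRX480 (-0.36), AT5G48570 (-0.21) and AGL24 (-0.16) did not pass.

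The array labelled wildtype replicate 2 stood apart from the others of its group. Its residual SD was 0.228 on the log2 scale, against 0.128 to 0.160 on the other 5 arrays. On it, 71 probe sets lay over 1 log2 unit above the mean of the other wild-type arrays where those agreed within 0.3, against 0 to 3 in the same comparison on each other array. In the opposite direction the largest number was 17, on ASL9-ox replicate 2. The named ones included seed storage and maturation genes, chosen after their values were seen. The oil body gene OLEO3 read 504 there and between 4.55 and 9.88 on the other 5 arrays, the storage protein gene PAP85 806 against 0.969 to 3.76, and AT3G15670, a late embryogenesis abundant protein gene, 309 against 0.276 to 5.06. Of the 71 probe sets, 5 were among the 7096 calls. Without wildtype replicate 2, 5943 probe sets passed, 5732 of them among the 7096, and 3433 were higher and 2510 lower.

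**Figure D3:**
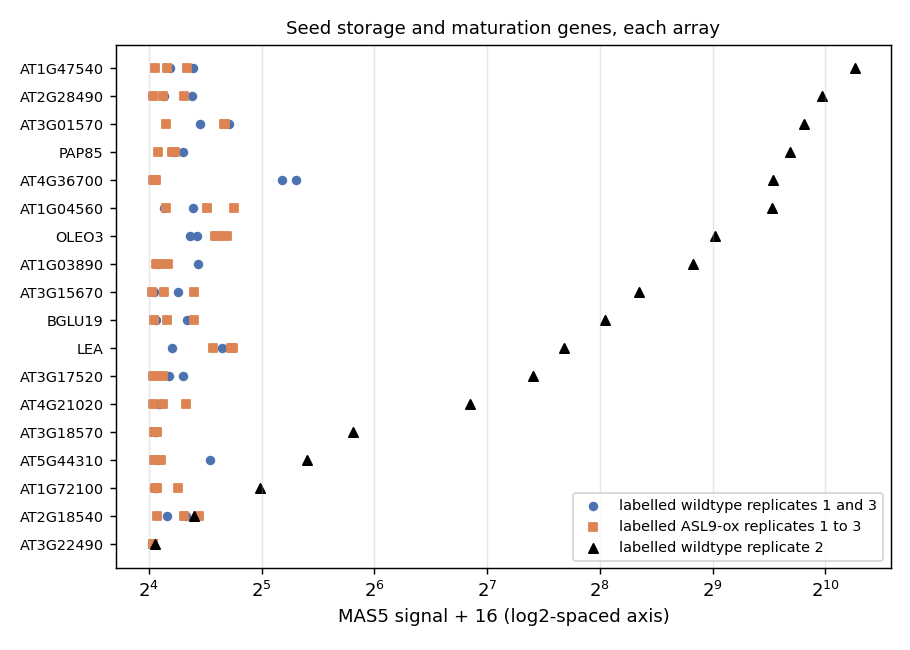
Signal plus 16 on each array, on a log2-spaced axis, for 18 seed storage and maturation genes. Triangles are wildtype replicate 2, circles the other wild-type arrays and squares the 3 arrays labelled ASL9-ox; OLEO3 reads 504 on wildtype replicate 2 and at most 9.88 elsewhere.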

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

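Centring on the hybridization controls was chosen after seeing the data; the other alternatives were planned. The total of 7096 calls lay between 5420 and 7268 under all alternatives at the threshold of 0.05, and 4569 probe sets passed at 0.01. Leaving out 1 array at a time gave 5560 to 6364 calls, 3220 to 3805 of them higher and 2340 to 2613 lower, 1173 to 1355 changed at least 2-fold, and 8 to 10 gene lists. Centring on the hybridization controls gave 2353 higher probe sets in place of 4203. A pseudocount of 1 gave 2098 changes of at least 2-fold and one of 64 gave 543, in place of 1218, by its effect on fold changes at low signals. With the dimmest 50% left out 5 of 7 lists that could be tested passed. With an estimated correlation in camera 0 of 14 passed, with a smallest unadjusted p of 0.0364. By fry, which tests a list against no change and not against other genes, 13 passed, a count that is not comparable with those of camera. For the other counts that moved the cause was not tested. With the replicate number as a block (replicate block) 6174 probe sets and 9 lists passed. Deviations of arrays with the same number correlated at -0.12, -0.06 and 0.02, so the numbers were not taken to pair the samples, and not every array correlated best with its own number. The 76 named genes gave 1279 values under 17 alternatives, of which 1259 stayed in the same direction and on the same side of the threshold and 0 reversed; 67 genes did so in every alternative that tested them, and 13 were not tested with the dimmest 50% left out. The 9 exceptions were PDF1.2 and BHLH101, YAB3, which passed without wildtype replicate 2 (adjusted p = 0.0444; 0.0444 to 0.454 over all alternatives), and EIN3, RTE1, PSBY, HEME1, HEME2 and SIM, which missed the threshold with centring on the hybridization controls. The fold change of ASL9 had no value under any setting, since no probe set was paired with it. Signals near the floor limit the fold changes of dim genes.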

Other observations

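Genes were also grouped by the letters that open their symbols, a grouping chosen after seeing the data. Among 42 families with at least 5 measured members, 2 passed camera. The UGT family of sugar-transferring enzymes was lower, with 17 of 33 members falling and 7 rising (adjusted p = 0.000953; adjusted p = 0.392 with an estimated correlation). UGT76E12 went from 126 to 1.79, UGT87A2 from 353 to 63.8 and UGT85A2 from 382 to 114.5, whereas UGT72E1 went from 80.1 to 144 (means, n = 3 per group). UGT74B1, UGT78D2 and UGT76C1 also belong to the lists fixed beforehand, as do UGT78D1 (0.13 on the log2 scale) and UGT76C2 (0.05), which did not pass. The IQD family of calmodulin-binding proteins was higher, with 11 of 12 members rising (adjusted p = 0.000953; adjusted p = 0.798 with an estimated correlation). The member iqd21 went from 75.3 to 184.5 and IQD30 from 38.5 to 80.5, and IQD26, at 0.20 on the log2 scale, did not pass. With centring on the hybridization controls 18 UGT genes fell and 4 rose, and 11 IQD genes rose.

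Except for the splits of the 6 arrays, the tests in this part were chosen after the results they bear on had been seen. The array labelled wildtype replicate 2 carried seed transcripts, and seed material in that sample is a candidate explanation. Of 7 seed storage and maturation genes whose values had not been seen when they were listed, 3 were at least 10 times higher on it than on every other array (AT1G03890 at 436.5, LEA at 189 and AT3G18570 at 40.1). This was too few to decide by the rule set. The other 11 seed genes, at 24.5 to 246 times the highest other array, had been picked from the 71 probe sets high on it and are no test. The 7 hold only seed genes outside those 71, which lowers the count that could be found among them. Among all 18 seed genes measured, 1 (AT4G36700) exceeded a signal of 16 on another array. Random noise of that array was argued against: those 3 of 7 genes lay over 1 log2 unit above every other array, as 66 of 7148 (0.923%) other probe sets below 16 on the other 5 arrays did (one-sided Fisher's exact test, p = 2.92e-05). No biological explanation was tested, because the design gives none within a group, and a sample mixed with other material stays open.

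Root tissue in the samples labelled wild type was considered for the joint fall of PYK10, lectin and peroxidase genes and rise of photosynthesis genes. The tissue label, aerial parts, would exclude roots, but the extraction protocol speaks only of harvested seedlings, and whether roots were removed from every sample is not known. The median log2 fold change of 10 measured root epidermis and root hair genes was -0.082. In the arrays labelled wild type 0 of them had a mean above 16 (the highest was AT4G08410 at 13.25), so they gave no sign of root tissue there. The rule set for this test could count against root tissue only with several of them above 16. Samples without roots could not have met it, so the rule decides nothing. The values themselves argue against root epidermis with root hairs in the samples labelled wild type. The median of the 10 genes there was 6.374, and none exceeded 16.36 on any array. Other root or hypocotyl tissue was not tested and stays open. EXPA7 and EXPA18 were also on the root list fixed beforehand. For 1 dilution factor shared by all photosynthesis and chlorophyll genes, 12 members with signals below 3000 were compared. Their log2 fold changes ran from 0.03 to 1.13, more than their errors allow if these are taken as known (Cochran Q = 152.4 with 11 degrees of freedom). This argues only against the same factor for all 12. An admixed tissue that expresses some of these genes would not give 1 factor, so dilution by such tissue stays open. An effect of the transgene stays open too, untested.

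The probe set 262704_at read 5101 on average in the arrays labelled wild type and 10.9 in those labelled ASL9-ox. Group labels exchanged between the 2 sets of arrays could give such a pattern if it read the transgene's transcript. In 0 probe sets did the median go from below 16 to above 1000 in the arrays labelled ASL9-ox, but this count restates the pattern, the level of ASL9 in wild type was not measured, and it decides nothing about group labels exchanged or not. On wildtype replicates 1, 2 and 3 the signal of 262704_at ranked 6, 2 and 4 from the top, control probe sets left out. Among probe sets with a median below 16 in the arrays labelled wild type, the highest median in those labelled ASL9-ox was 160.6. The gene read by 262704_at is not named in the annotation used, and neither is a probe set for ASL9. Exchanged labels and a loss of this transcript in the transgenic line therefore cannot be told apart here. Until that gene is known, every direction given stays provisional. Under exchanged labels every direction given for this comparison would turn around, with its size unaltered.

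The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 7096 calls, 4203 and 2893 in the 2 directions and 1218 of at least 2-fold, and the other 9 gave 0 in limma (103 to 328 probe sets had an unadjusted p below 0.05). Each of those 9 puts arrays of both labels on each side. The difference between the labelled groups then enters the spread and lowers the calls, so the 0 is no measure of chance alone. For each of these counts 1 split of 10 was as large, the real one. For gene lists it was 1 of 10 too, with 9 lists in the real split and at most 2 in the others.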
